A study of Homo sapiens with 6 samples.

How the data were processed

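The labels place 6 libraries of total RNA from AGS cells in 2 groups by their treatment, 3 with shControl and 3 with shUSP1. Replicates are numbered 1 to 3 in the order of the samples. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels' protocol speaks of 3 groups of cells where the treatments give 2. The labels name no second hairpin.

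The values are FPKM per gene, fragments scaled for transcript length and for the library's mapped total, as deposited by the authors in a single table with a column for each library. Per the labels' protocol, reads of low quality, adapter reads and reads with over 5% unknown bases were removed after FastQC. Per the submitters' processing notes, Bowtie2 and genome build hg38 were used. The versions, the quantifier, the gene annotation release, the library kit and its strand setting were not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and members of near-identical families such as HLA genes, histones and metallothioneins are uncertain. Low values are not whole multiples of a step, so read counts could not be recovered, depth is unknown, and no count model was used. The columns of values not mapped to a sample numbered 0.

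The table held 60737 rows, of which 132 repeated an Ensembl identifier and were removed, leaving 60605 genes. Genes with a mean FPKM of at least 1 over the 6 libraries were kept, 11376 in all. Values were used without further scaling as log2(FPKM + 1), a scale that understates the change of low genes. The groups were compared with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Intervals are at 95%. Coordinates came from GENCODE release 29 on GRCh38, the same assembly as hg38, matched by Ensembl identifier for 11339 of the 11376 genes.

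Before the data were examined, 40 gene lists were fixed from textbook knowledge, with 760 entries (older and newer symbols of a gene both entered), of which 738 were found in the table and 597 were tested. Where a symbol had several rows, the row with the highest mean was used. The 34 lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Of the others, the mesenchymal, metallothionein, fibroblast, leukocyte, endothelial and hepatocyte lists had 4, 2, 2, 1, 0 and 4 tested members. The rule for named genes, also fixed before, took USP1. It took genes past the threshold or, where none passed, the 6 with the smallest unadjusted p in each direction among genes with a mean FPKM of at least 5 and no overlap between groups, without unnamed loci. For each called list without a member past the threshold it took the 2 members with the highest mean, and for the USP1 partner, Fanconi anemia, p53 and BMP lists the 3 with the smallest p. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

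Titles carry no suffix, 1 or 2 in each group, and the pairing used here comes from these suffixes, not from a statement of shared days. The deviations of libraries from their group means correlated at 0.565, 0.57 and 0.159 across genes in the 3 pairs, all above the 0.1 set for treating the libraries as paired. Shared suffixes were not each library's best match, since shUSP1 replicate 3 correlated at 0.287 with shControl replicate 2 and at 0.159 with shControl replicate 3. The main fit has no block, as fixed before, and the blocked fit is an alternative. With 3 pairs the smallest two-sided exact sign-flip p is 0.25.

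The alternatives fixed before were pseudocounts of 0.1 and 0.5, no low-value filter, a mean FPKM of at least 5, rescaling to a sum of 1000000, rescaling by the median ratio, quantile normalization, no trend, robust estimation, library quality weights, the replicate block, each library left out, a 2-fold minimum, an adjusted p below 0.01, camera with an estimated correlation, and fry. After seeing the data, covariates for the ATF4 list mean and the first residual component were added, as was a fit without the 3 libraries with the highest ATF4 list means. That fit leaves 1 shControl library, which is assumed to vary like the shUSP1 libraries. The lists of MHC class I genes and of RNA polymerase III transcripts were also written after. A test of the title suffix as a cause of the largest division of the libraries was first run on the correlation of deviations alone. When its outcome was known, 2 further tests on the ATF4 list means of the pairs were added, with a limit of 1.01, which is 0.5 times the range of the pair means, and all 3 outcomes are reported.

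The fit was tested on simulated data with the 11376 genes of shUSP1 against shControl. With independent noise it recovered 38% of 100 genes changed by 1 log2 unit and 88% of 100 genes changed by 2, with 6 false calls. With noise that held the first residual component it recovered 25% and 78%, with 5 false calls. Both sets of 100 genes were changed at once, which eases the Benjamini-Hochberg adjustment. The shares recovered therefore do not give the power to find a few changed genes. USP1, with a log2 difference of -2.11 in the real data, had a limma adjusted p of 0.222.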

Results

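Gene expression was measured by RNA sequencing in AGS, a human gastric adenocarcinoma cell line, in 2 groups of 3 libraries. One group carried a control short hairpin RNA (shControl) and the other a hairpin against USP1 (shUSP1). USP1 is a deubiquitinase that works with its cofactor WDR48 and removes ubiquitin from FANCD2, a DNA crosslink repair protein, and from PCNA, the sliding clamp of DNA replication. The deposited values are FPKM per gene, so the read depth of each library is unknown and no counting error can be attached to a level. The FPKM of a library summed to between 392129 and 437518, and between 11111 and 11419 genes reached an FPKM of 1. The comparison asks how lowering USP1 changes the transcriptome of these cells, in a series concerned with USP1 in the progression of gastric cancer.

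The targeted gene was lower in all 3 shUSP1 libraries. USP1 (ENSG00000162607, GRCh38 chromosome 1, 62436297 to 62451804, plus strand, protein coding) stood at 36.9, 26.5 and 20.2 FPKM in shControl replicates 1, 2 and 3 and at 6.20, 6.78 and 3.89 FPKM in shUSP1 replicates 1, 2 and 3. The group means were 27.9 ± 8.45 FPKM (SD, n = 3) and 5.62 ± 1.53 FPKM (SD, n = 3), a 4.96-fold lower level in shUSP1. On the log2(FPKM + 1) scale USP1 fell by 2.11 (SE 0.27), with an unadjusted limma p of 3.79e-05 for this gene chosen in advance, the smallest p of the 11376 genes tested. After Benjamini-Hochberg adjustment over all genes its limma p was 0.222. An exact two-sided permutation test of the 6 libraries gave p = 0.1, which is the smallest that 3 against 3 can give.

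**Figure D1:**
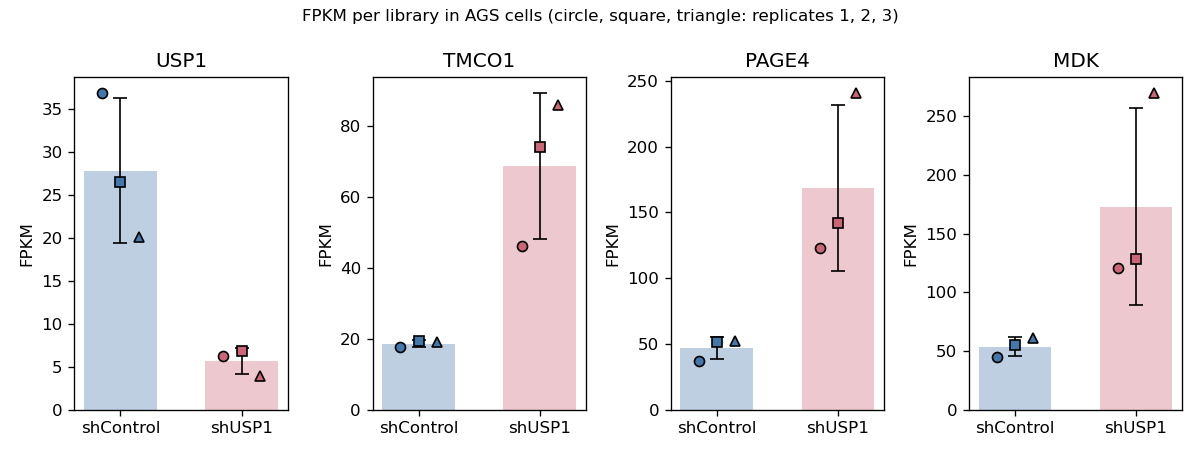
FPKM (vertical axes) of USP1, TMCO1, PAGE4 and MDK in the 3 shControl and 3 shUSP1 libraries. Bars are group means, error lines are 1 SD (n = 3) and points are libraries. The groups do not overlap for any of the 4 genes, which for TMCO1, PAGE4 and MDK was a condition of their choice.

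No gene passed the adjusted threshold over the transcriptome. With limma on 11376 genes, 0 were called at an adjusted p below 0.05, and the smallest adjusted p was 0.222. At an unadjusted p below 0.05 there were 314 genes, 142 higher and 172 lower in shUSP1, where 568.8 are expected by chance. Of these 314 genes, 49 differed at least 2-fold, 31 higher and 18 lower. With the libraries blocked by title suffix the unadjusted number was 699, and the number called stayed at 0. The groups did not overlap for 757 genes, or 6.65%, where chance gives 10%. Without the low-value filter 12 genes were called, with USP1 and TMCO1 not among them (limma adjusted p of 0.537 for each). With library quality weights 4 were called: USP1, TMCO1, C1R and RP11-16N10.2, all but USP1 and TMCO1 being named after their values were seen. Leaving out shUSP1 replicate 1 gave 2 calls and leaving out shUSP1 replicate 2 gave 1.

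Among named genes with a mean FPKM of at least 5 and no overlap between groups, those with the smallest unadjusted p that were higher in shUSP1 were TMCO1, PAGE4, RPPH1, MEA1, MDK and COMMD8. C1R, below that level and chosen after its values were seen, had an unadjusted limma p of 7.80e-05, against 7.30e-05 for TMCO1. TMCO1, an endoplasmic reticulum calcium channel (chromosome 1, 165724293 to 165827755), averaged 18.6 ± 0.927 FPKM in shControl and 68.7 ± 20.5 FPKM in shUSP1 (SD, n = 3 each), a log2 difference of 1.79 (SE 0.25). Its limma adjusted p was 0.222, and it passed at 0.0117 with library quality weights and at 0.0189 without shUSP1 replicate 1. PAGE4, a cancer/testis antigen on the X chromosome (49829260 to 49833973), averaged 46.9 ± 8.42 and 168.6 ± 63.3 FPKM, a log2 difference of 1.78. MEA1 averaged 62.3 and 177.6 FPKM (log2 difference 1.51), and MDK, the growth factor midkine, averaged 53.6 and 172.8 FPKM (log2 difference 1.58). COMMD8 averaged 3.89 and 8.36 FPKM (log2 difference 0.95). A noncoding RNA row that carries the symbol RPPH1 (ENSG00000259001, chromosome 14, 20343048 to 20343685, minus strand) averaged 15.1 and 41.9 FPKM (log2 difference 1.39). That row covers the RPPH1 ribozyme gene itself (20343075 to 20343407), whose own row never exceeded 0.183 FPKM, and reads of the RPPH1 ribozyme and of the overlapping noncoding RNA cannot be separated.

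Those lower in shUSP1, besides USP1, were BICD1, ZNF608, CERS6, BAMBI and PPP6R3. BICD1, a dynein adaptor of vesicle transport, averaged 8.76 FPKM in shControl and 3.45 FPKM in shUSP1, a log2 difference of -1.09. The transcription regulator ZNF608 averaged 14.4 and 8.04 FPKM (log2 difference -0.78), and the ceramide synthase CERS6 averaged 16.7 and 9.39 FPKM (log2 difference -0.79). BAMBI, a pseudoreceptor that restrains TGF-beta family signalling, averaged 57.0 ± 6.10 and 33.5 ± 5.26 FPKM (SD, n = 3 each), a log2 difference of -0.75. PPP6R3, a regulatory subunit of protein phosphatase 6, averaged 54.4 and 31.6 FPKM (log2 difference -0.77). Over these 12 genes the limma adjusted p was 0.222 for USP1 and TMCO1, 0.41 for PAGE4 and RPPH1, and 0.54 for MEA1. For MDK, COMMD8, BICD1, ZNF608, CERS6, BAMBI and PPP6R3 it was 0.99997.

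The lists of genes that work with USP1 showed no shift as groups. Of 14 USP1 partners and substrates tested, 6 were higher and 8 lower, with a median log2 difference of -0.04 and a mean of 0.03, which differ in sign, and 0 passed the threshold. FANCD2 averaged 5.68 and 4.78 FPKM, ATAD5, which unloads PCNA, averaged 4.43 and 3.21 FPKM, and ID1, a helix-loop-helix inhibitor of differentiation, averaged 6.80 and 14.5 FPKM with 26.6 FPKM in shUSP1 replicate 3 alone. Of 20 Fanconi anemia genes, 8 were higher and 12 lower (median log2 difference -0.02). Among them CENPS averaged 22.6 and 17.5 FPKM and FANCG 5.01 and 6.05 FPKM. Medians were -0.07 for 22 homologous recombination genes and -0.06 for 13 translesion synthesis genes. Of 22 p53 targets, 14 were higher and 8 lower (median 0.04), with CDKN1A at 21.9 and 28.6 FPKM, FDXR at 12.4 and 18.7 FPKM and PLK3 at 2.94 and 3.54 FPKM. Of 7 BMP and ID targets, 5 were higher and 2 lower. BAMBI was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.0376), a value not adjusted for the 34 lists tested. Over all genes the limma adjusted p of BAMBI was 0.99997. SMAD7 averaged 1.43 and 1.87 FPKM.

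Genes induced by interferon were higher in shUSP1. All 25 tested members of the interferon-stimulated list had a positive difference, with a median of 0.97 and a mean of 1.07 on the log2 scale, and 21 of the 25 were higher within each of the 3 pairs. Of all 11376 genes tested, 1569 were higher in each pair, but the members of this list moved together and do not count as independent. ISG15, a ubiquitin-like protein, averaged 91.1 ± 54.2 FPKM in shControl and 242.6 ± 165.0 FPKM in shUSP1 (SD, n = 3 each). Chosen after their values were seen, IFIT3 averaged 10.1 and 40.3 FPKM, IFI44 2.37 and 13.3 FPKM, and RSAD2 1.07 and 7.15 FPKM. No member passed over all genes or adjusted over the list alone, where the smallest limma adjusted p was 0.0865. The competitive camera test with a preset correlation called the list at an adjusted p of 1.95e-21. With an estimated correlation of 0.727 between members the list was not called (adjusted p = 0.767), and fry gave an adjusted p of 0.95. Without shUSP1 replicate 3 the list mean was 0.70.

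The spread between libraries of a group was as wide as the difference. Relative to the mean of the 6 libraries, the list mean was -0.99, 0.13 and -0.75 in shControl replicates 1, 2 and 3 and -0.44, 0.77 and 1.28 in shUSP1 replicates 1, 2 and 3. Within the pairs that share a title suffix the difference was 0.55, 0.64 and 2.03. An exact permutation test of the list means gave p = 0.2. The libraries also differed in the unfolded protein response and ATF4 list, whose mean was 1.00, -0.999 and 0.44 in shControl and 1.17, -0.89 and -0.72 in shUSP1. The 3 libraries with the highest ATF4 list means had the 3 lowest interferon list means. The hepatocyte marker FGA, at 46.1, 53.03 and 91.5 FPKM in the other 3 libraries, did not exceed 10.3 FPKM in these. The ATF4 list was not called between the groups (camera adjusted p = 0.208) and was called with the pairs as a block (adjusted p = 0.0222), where an estimated correlation gave an adjusted p of 0.861.

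**Figure D2:**
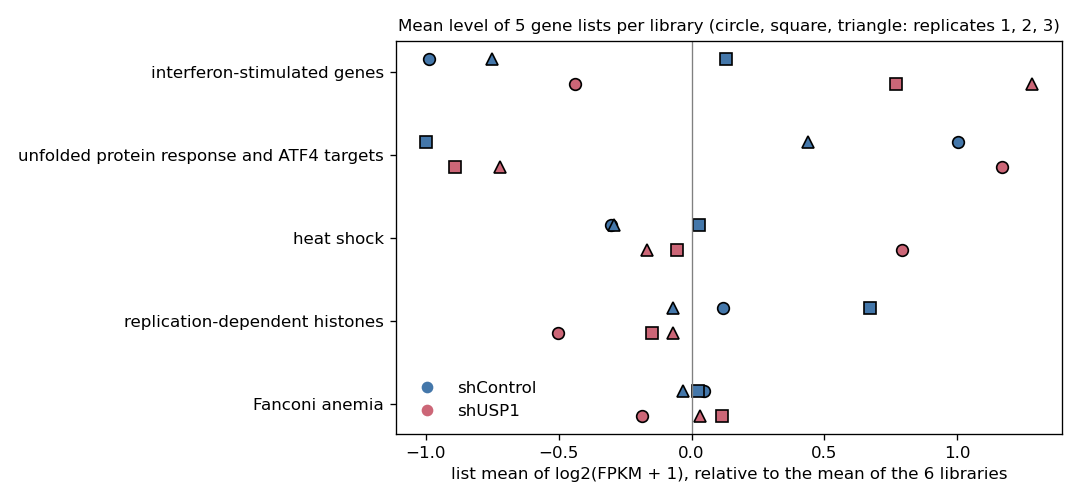
Mean of log2(FPKM + 1) of 5 gene lists in each library (horizontal axis), relative to the mean of the 6 libraries. Points are libraries, and the interferon-stimulated list runs from -0.99 in shControl replicate 1 to 1.28 in shUSP1 replicate 3, while the ATF4 list splits both groups.

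Camera with the preset correlation called 8 of the 34 lists tested, the interferon-stimulated list among them. Each of the 10 ways to split the 6 libraries 3 and 3 called at least 8 lists, so this number does not set the hairpin apart. With an estimated correlation none of the 8 was called, with an adjusted p of 0.767 for the interferon, histone and NF-kB lists and an adjusted p of 0.877 for the other 5, and fry called 0. Replication-dependent histones were lower, 7 of 7 members with a median of -0.51 on the log2 scale, H1-2 at 11.8 and 9.35 FPKM and H2BC12 at 8.22 and 4.87 FPKM. Cytosolic ribosomal proteins were lower in 36 of 38 members, by little (median -0.19), with RPL5 at 2278 and 1885 FPKM. NF-kB targets were higher in 8 of 10 (median 0.21), with the NF-kB inhibitor NFKBIA at 17.6 and 24.2 FPKM and the adhesion molecule ICAM1 at 8.08 and 11.1 FPKM, neither overlapping between groups. Heat shock genes were higher in 12 of 13 (median 0.40), with the chaperones HSP90AA1 at 1644 and 2492 FPKM and HSP90AB1 at 1641 and 1884 FPKM. Glycolysis genes were higher in 16 of 16 (median 0.33), with GAPDH at 620.2 and 776 FPKM and ENO1 at 574 and 718 FPKM. Nuclear oxidative phosphorylation genes were higher in 30 of 31 (median 0.15), with COX4I1 at 594 and 625 FPKM and COX7C at 516 and 524 FPKM, and proteasome subunits in 25 of 28 (median 0.13), with PSMC1 at 342 and 386 FPKM while PSMC3, at 181.2 and 181.4 FPKM, was among the 3 negative members (log2 difference -0.03). In the pairs without a suffix, with suffix 1 and with suffix 2, the list means differed by -0.62, -0.82 and -8.26e-04 for histones, -0.10, -0.12 and -0.27 for ribosomal proteins, and 0.36, 0.13 and 0.35 for NF-kB targets. A single pair carried most of the difference of the other 4 lists, at 1.10, -0.08 and 0.12 for heat shock, 1.15, 0.00276 and -0.12 for glycolysis, 0.02, -0.00691 and 0.41 for oxidative phosphorylation, and -0.05, -0.06 and 0.47 for proteasome subunits. Members higher in all 3 pairs numbered 1 of 13, 2 of 16, 7 of 31 and 5 of 28 in these 4 lists, where 1569 of all 11376 genes tested were.

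With each library left out in turn, the interferon and NF-kB lists were still called with the preset correlation, a call that neither kept with an estimated correlation (adjusted p = 0.767). The histone call ended without shControl replicate 2 (adjusted p = 0.0577), where the median was -0.16. The ribosomal call ended without shControl replicate 3 (adjusted p = 0.767) or shUSP1 replicate 2 (0.569), and its median ran from -0.33 without shControl replicate 2 to -0.02 without shControl replicate 3. The glycolysis call ended without shControl replicate 1 (0.14) or shUSP1 replicate 1 (0.535), and its median ran from 0.15 without shControl replicate 1 to 0.60 without shControl replicate 3. The heat shock call ended without shUSP1 replicate 1 (adjusted p = 0.999), whose list mean was 0.79 against -0.30 to 0.03 in the other libraries, and without shControl replicate 1 (0.06) or 3 (0.0757). Without shUSP1 replicate 1 the heat shock median was 0.08 and the log2 difference of HSP90AA1, at 4147 FPKM in that library, was 0.07 in place of 0.52. The oxidative phosphorylation call ended without shControl replicate 1 (adjusted p = 0.443) or shUSP1 replicate 3 (0.883), with medians from -0.01 without shUSP1 replicate 3 to 0.30 without shUSP1 replicate 1. The proteasome call ended without shControl replicate 1 (adjusted p = 0.463) or 3 (0.49) and without shUSP1 replicate 2 (0.227) or 3 (0.82), with medians from -0.00721 without shUSP1 replicate 3 to 0.33 without shUSP1 replicate 1.

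Other settings moved the 7 lists besides the interferon list. Without the low-value filter the median was 0.04 for NF-kB targets (adjusted p = 0.075) and -0.14 for histones, which stayed called, and the heat shock (adjusted p = 0.075) and proteasome (adjusted p = 0.1) calls ended. With library quality weights the medians were -0.22 for histones, -0.34 for ribosomal proteins, 0.34 for NF-kB targets and 0.23 for proteasome subunits, all called, and the heat shock (0.24, adjusted p = 0.29) and glycolysis (-0.0139, adjusted p = 0.971) calls ended. Quantile normalization ended the proteasome call (0.08, adjusted p = 0.152). In settings chosen after seeing the data, the ATF4 covariate ended the oxidative phosphorylation (0.09, adjusted p = 0.0629) and proteasome (0.04, adjusted p = 0.211) calls. Leaving out the 3 libraries with the highest ATF4 list means ended the NF-kB (0.16, adjusted p = 0.134), ribosomal (0.0506, adjusted p = 0.66), heat shock (-0.106, adjusted p = 0.195), oxidative phosphorylation (0.15, adjusted p = 0.134) and proteasome (0.06, adjusted p = 0.896) calls.

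**Figure D3:**
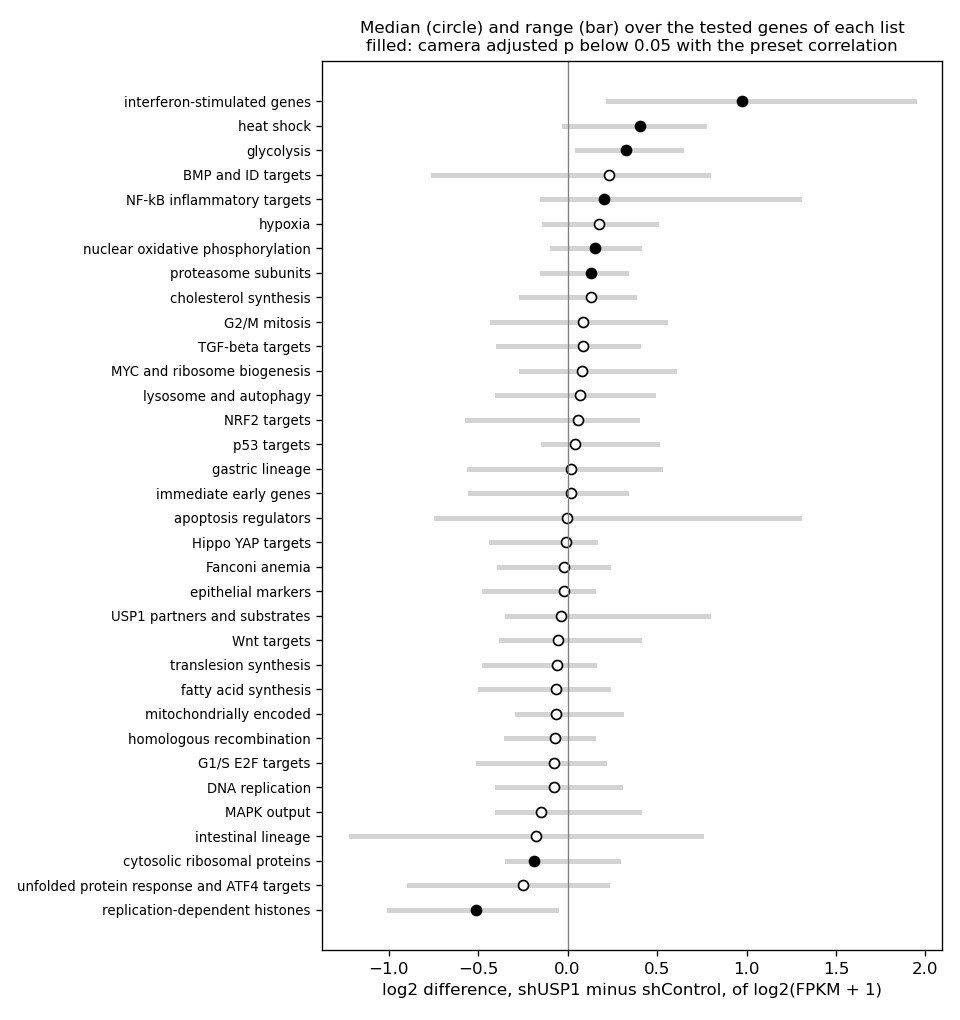
Median (circle) and range (bar) of the log2 difference, shUSP1 minus shControl, over the tested genes of the 34 lists. Filled circles mark the 8 lists that camera called with the preset correlation, from the interferon-stimulated genes at 0.97 to the replication-dependent histones at -0.51.

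Proliferation, signalling and lineage lists were not called in the main fit. Some settings called lists outside the main 8, which are not named here. Library quality weights called 14 lists, of which 6 were among the 8. Without shControl replicate 2, 13 were called (7 among the 8), and without shUSP1 replicate 1, 12 were called (6 among the 8). The camera adjusted p was 0.208 for G2/M mitosis (median 0.09), and medians were -0.08 for DNA replication, -0.07 for G1/S E2F targets, 0.13 for cholesterol synthesis, -0.06 for fatty acid synthesis, 0.08 for MYC and ribosome biogenesis, 0.17 for hypoxia and 0.06 for NRF2 targets. They were -0.15 for MAPK output, 0.02 for immediate early genes, -0.05 for Wnt targets, -0.01 for Hippo YAP targets, 0.09 for TGF-beta targets, 0.07 for lysosome and autophagy genes and -0.00375 for apoptosis regulators. Medians were -0.02 for epithelial markers, -0.07 for mitochondrially encoded genes, 0.02 for the gastric lineage and -0.18 for the intestinal lineage. Means were of the other sign for immediate early genes, the gastric lineage and apoptosis regulators. Markers of other cell types were mostly below 1 FPKM. Of 9 endothelial markers 0 reached a mean of 1 FPKM, of 11 leukocyte markers CD68 alone did, of 11 fibroblast markers PDGFRA and COL1A1 did, and of 11 hepatocyte markers APOA2, FGB, FGA and APOA1 did, in either group. The apolipoprotein APOA2 averaged 218.6 and 175.2 FPKM, while albumin (ALB) was listed at 0 in all 6 libraries. The fibrinogen chain FGA stood at 8.49, 46.1 and 7.15 FPKM in shControl and at 10.3, 53.03 and 91.5 FPKM in shUSP1 replicates 1, 2 and 3, and so was highest in the 3 libraries with the highest interferon list means. FGB stood at 23.2, 77.8 and 14.9 FPKM in shControl and at 15.9, 27.9 and 98.0 FPKM in shUSP1. Of 17 mesenchymal markers, 4 reached it (MMP14, S100A4, ITGA5 and VIM), as did 2 of 8 metallothioneins (MT2A and MT1X).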

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

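The covariates and the fit without 3 libraries were chosen after seeing the data. USP1 stayed lower in all 20 alternatives, from -2.31 without shControl replicate 3 to -1.89 without shControl replicate 1, with limma adjusted p from 0.0384 (quality weights) to 0.748 (without shControl replicate 3). Genes called numbered 0 except with no low-value filter (12, 6 higher and 6 lower), quality weights (4, 2 higher and 2 lower), the 3 libraries with the highest ATF4 list means left out (1, lower), and single libraries left out (0 to 2 called, 0 to 2 higher, 0 to 1 lower). Without the filter 36264 genes were tested. Lists called numbered 8, against 5 without the filter, 14 with quality weights, 4 (without shControl replicate 1) to 13 (without shControl replicate 2) with a library left out, and 0 with an estimated correlation or fry. The interferon list mean stayed positive, 0.70 (without shUSP1 replicate 3) to 1.56 (without shUSP1 replicate 1), and at 1.07 it was no longer called with an estimated correlation or by fry. The replicate block called 0 genes and 9 lists, the 8 and the ATF4 list, and changed no other call. It left USP1 at -2.11 and the interferon list at 1.07, as it must, since each pair holds 1 library of each group. Fits without trend, with robust estimation or with the first residual component likewise cannot change these estimates. Their unchanged values are therefore no sign of stability.

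Of 153 alternatives of the 7 other called lists, 112 kept direction and call, 36 lost the call and 5 turned sign. Ribosomal proteins had a median of 0.0506 and heat shock genes -0.106 without the 3 libraries, glycolysis -0.0139 with quality weights, and with a library left out oxidative phosphorylation ran from -0.0115 (without shUSP1 replicate 3) to 0.297 and proteasome subunits from -0.00721 (without shUSP1 replicate 3) to 0.330. Of 717 alternatives of named genes, 698 kept direction and stayed uncalled, 2 of TMCO1 became called, and 17 turned sign. No named gene was called in the main fit, and the 698 include fits that cannot change an estimate, so this number is no measure of stability. Quality weights gave GAPDH -0.0316, PSMC3 0.195 and PLK3 -0.0112. Without the 3 libraries HSP90AA1 stood at -0.45, HSP90AB1 at -0.11, COX7C at -0.19 and PSMC1 at -0.21. With the ATF4 covariate COX4I1 was at -0.00892 and COX7C at -0.0122, and quantile normalization gave COX7C -0.0366. With a library left out COX4I1 ran from -0.15 to 0.23, COX7C from -0.10 to 0.17, PSMC1 from -0.00174 to 0.51 and PSMC3 from -0.15 to 0.22. The cause was not tested. Depth, unknown here, sets no limit that can be given.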

Other observations

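The interferon list and its camera test were fixed before the data were examined. The splits, the covariate and the single-library limit applied to its mean were chosen only after the results were seen, as were the tests of the MHC class I list, of the title suffix and of RPPH1. The tests of the numbers of genes and lists and of transcript length and GC were planned.

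MHC class I antigen presentation genes, a list written after the data were seen, were higher in shUSP1 for 12 of 12 tested members, with a median log2 difference of 0.61. HLA-B averaged 24.9 ± 5.67 FPKM in shControl and 67.9 ± 33.5 FPKM in shUSP1 (SD, n = 3 each), HLA-F averaged 6.37 and 18.9 FPKM, and neither overlapped between groups, as for 3 of the 12. B2M, the light chain of MHC class I, averaged 119.3 and 189.1 FPKM, and the peptide transporter TAP1 averaged 4.03 and 8.19 FPKM. With an estimated correlation of 0.786 camera gave an unadjusted p = 0.0762, which is not an independent test of a list written after the data were seen. None of these genes is in the interferon-stimulated list, but whether the MHC class I genes vary apart from that list was not tested. Of the 10 splits of the 6 libraries, 3 gave a list difference as large as the 0.68 between the groups, the highest other being 0.73, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 pairs the highest other was 0.43, but 4 splits are fewer still and the list was written after the data were seen.

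Other genes that did not overlap, chosen after their values were seen, were the amyloid precursor APP (367.5 and 608 FPKM) and its relative APLP2 (436.8 and 755 FPKM), the metallothionein MT2A (26.4 and 81.5 FPKM, 151.8 in shUSP1 replicate 1), and the complement protease C1R (1.08 and 4.21 FPKM). Also chosen after their values were seen, the imprinted noncoding RNA H19 and 2 heat shock genes differed widely between libraries. H19 ranged from 571.7 FPKM in shControl replicate 2 to 6239 FPKM in shUSP1 replicate 1. Heat shock genes stood apart in shUSP1 replicate 1, where HSPA1A was at 844.8 FPKM against 70.8 to 132.9 FPKM in the other 5 libraries and DNAJB1 at 390.5 against 46.8 to 94.5 FPKM.

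The largest structure of the libraries did not follow the hairpin. The first principal component held 50.5% of the variance, and the split of shControl replicates 1 and 3 with shUSP1 replicate 1 from shControl replicate 2 with shUSP1 replicates 2 and 3 called 342 genes, where the real split called 0, which points to a structure of the samples. Among its leading genes, chosen after their values were seen, the stress transcription factor DDIT3 stood at 104.9, 103.4 and 169.5 FPKM in the first 3 libraries and at 8.91, 10.97 and 7.64 FPKM in the others, and the asparagine synthetase ASNS at 31.7, 18.8 and 33.7 against 2.05, 2.08 and 1.95 FPKM, while FGA was higher in the others (log2 difference 2.69, limma adjusted p = 0.00318). This split was picked because it called the most genes, so p-values within it describe the split and are not an independent test. Transcript length and GC content were only weakly related to this split, with Spearman correlations across 11339 genes of -0.062 and 0.138, under the 0.3 in size set before. For shUSP1 against shControl they were -0.115 and 0.132. FPKM is already scaled for length, so a weak correlation with exonic length cannot rule out a part played by length. A shared day or batch marked by the title suffix is a candidate explanation, since the lowest correlation of deviations in a pair was 0.159 and the ATF4 list mean differed by at most 0.165 in the pairs without a suffix and with suffix 1, but the pair with suffix 2 differed by 1.16, over the limit of 1.01 (0.5 times the range of the pair means), and lies on both sides. What set that pair apart stays open, such as differences in medium or density, which were not tested.

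The interferon-stimulated genes were higher in shUSP1 by a list mean of 1.07. The tables argue against a single library, since the lowest value with a library left out was 0.70. With the ATF4 list mean as a covariate, chosen after the data were seen, the difference was 0.88. The 95% interval of that linear model on 6 list means was 0.145 to 1.61, while the exact permutation test without a covariate gave p = 0.2. The interval rests on 6 libraries and an assumed straight-line relation, so it cannot decide whether the ATF4 axis was the whole cause. Of the 10 splits, 2 gave as large a difference, the highest other being 1.45 for the split that called 342 genes, and 10 splits are too few for a share under 0.05. That split keeps 2 of the pairs together, and among the 4 splits that part all 3 pairs the real value of 1.07 stood above the highest other, 0.71, and the genes at an unadjusted p below 0.05 numbered 314 against 154 without the block but 699 against 632 with it. The pair with suffix 2, which lies on both sides of the split that called 342 genes, had the largest pair difference, 2.03 against 0.55 and 0.64. A part played by the structure between libraries, chance, lower USP1 and another effect of the hairpin all stay open. No second hairpin or rescue was analysed here.

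The noncoding row named RPPH1 was higher in shUSP1 by 1.39 on the log2 scale. The other 6 RNA polymerase III transcripts had a median difference of -0.10 (SD 0.26) and ran from -0.59 for RN7SK to 0.12 for RMRP. RNY4 (1.46 FPKM in shControl and 1.67 in shUSP1), RNY1 (1.05 and 0.88) and RMRP (0.79 and 0.96) were near the floor. At such low levels the scale understates change, so these cannot tell. The better measured RN7SK, RN7SL1 and RN7SL2 were lower in shUSP1, at -0.59, -0.09 and -0.12. They argue against a general gain of such transcripts, for these genes only. The row overlaps the ribozyme gene and the start of PARP2, so which RNA was higher stays open.

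With 0 genes called between the groups, any split gives at least as many (10 of 10, in all and in each direction), so that comparison says nothing about chance. The highest other split called 342 genes, 200 in a direction. For lists, all 10 splits gave at least the 8 called, the highest other being 14. The number of lists called with the preset correlation was thus no larger than in any other split, and does not set the hairpin apart. Among the 4 splits that part all 3 pairs, the others called at most 1 gene and up to 11 lists.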
